A study of Homo sapiens with 18 samples.

How the data were processed

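RNA splicing was measured by RNA sequencing in A549, a human lung adenocarcinoma cell line. Per the labels' protocols, cells stably expressed a scrambled hairpin (SCR) or either of a pair of short hairpin RNAs against hnRNP M (sh1 and sh2), and received TGFβ at 5 ng/ml for 72 h or no TGFβ. Each of the 6 groups held 3 libraries, 18 in all. Per the labels' protocols, RNA was extracted with TRIzol, ribosomal RNA was depleted, libraries were made with a strand-specific kit, and paired reads of 150 bp were obtained on a NovaSeq instrument. Per the submitters' processing notes, the tool STAR and the genome build hg19 were used; no version of STAR is given there. The tool that computed the splicing values is not given in the sources used here.

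The deposited table gives, for each splicing event and library, a percent spliced in (PSI) written as a fraction from 0 to 1. It holds 7 kinds of event, namely skipped exon (SE), alternative first exon (AF), alternative last exon (AL), alternative 3′ splice site (A3), alternative 5′ splice site (A5), retained intron (RI) and mutually exclusive exons (ME). Coordinates are hg19 and are given as in the table. For retained introns they were taken as the exon bases on either side, so the intron lies between them. To find which form each PSI counts, mean PSI was correlated with that of skipped exon events that use the same junctions. PSI followed the junction with the shorter intron in A3 (r = 0.936 over 765 events), A5 (r = 0.920, 907 events), AF (r = 0.957, 2061 events) and AL (r = 0.966, 1408 events), and the exon listed second in ME (r = 0.757, 1849 events). PSI was read as inclusion of the exon in SE and as the retained share in RI, which was assumed and not checked. These correlations run across events, which are not independent replicates.

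No read number per event is given, so the depth behind each PSI is unknown and no counting interval was computed. PSI compares forms of one gene and does not measure its level. No value was missing. Between 46.1% and 50.8% of the values in a library stood at exactly 0 or 1, and 19.4% to 22.0% were listed at 0. An exact 0 can be a true absence of one form or an estimate from very few reads or none. For a single event these cannot in general be separated without read numbers. Some pairs of skipped exon events share a junction, which skips the exon in 1 event and includes it in the other. Between 194 and 390 such pairs per library were both at 0. This implies that 1 event of the pair had no junction read, so events without reads can be listed at 0.

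The table held 103102 lines. After removal of 248 repeated events and 2566 events with the same PSI in all 18 libraries, 100288 events of 14438 genes were tested (47820 SE, 16024 AF, 11129 A3, 10161 A5, 6676 RI, 5763 AL and 2715 ME). Of 14619 gene identifiers, 14426 matched the current naming table, and 316 of 318 gene names that a spreadsheet had turned into dates were restored from it. All 18 columns of values matched a sample title.

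Each event was tested with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8) on the PSI scale, in one model with a mean for each of the 6 groups and with a moderated variance that allowed for a trend and for outlying events. The 9 contrasts were the TGFβ response in SCR, sh1 and sh2, the effect of each shRNA without and with TGFβ, and the interaction of each shRNA with TGFβ, which is the knockdown response minus the SCR response. An event was called when its Benjamini-Hochberg adjusted p over the 100288 events was under 0.05 and its difference of mean PSI was over 0.1, the size limit stated in the series' own design text. With 3 libraries against 3, an exact two-sided permutation test cannot go below 0.1 for any single event, so the limma tests rest on a model of the spread. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

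To test the procedure, unchanged groups were simulated from the mean and residuals of each event. Changes of known size were added to simulated events with a mean PSI between 0.4 and 0.6 and an SD under 0.2. For the SCR response 10% of changes of 0.2 were called, 28% of 0.3 and 55% of 0.5 (100 events each among 100288). Beside them 17 unchanged events were called. Comparisons in which nothing was changed gave 8 to 10 false calls, so the adjusted p-values of limma were too small in these simulated data. For a true slope of 0.6 between responses, the slope over separately chosen libraries came out at 0.0861, whereas an instrumental slope gave 0.584 and a noise-corrected slope 0.584 (15725 events). In the gene list test, 2 of 100 random lists had a permutation p under the limit of 0.05. For the 20 genes with the most events, the permutation test gave 0.198 with matching on the number of events and 1e-04, the smallest possible, without it.

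The groups, contrasts, thresholds, alternatives, 11 gene lists and the rule for named genes were set before the data were examined. The lists were the EMT and epithelial splicing program, the hnRNP family, SR proteins and other splicing regulators, TGFβ and SMAD signalling, actin cytoskeleton and motility, cell adhesion and junctions, extracellular matrix, vesicle trafficking and exocyst, cell cycle and DNA repair, apoptosis, and markers of other cell types (immune, endothelial, fibroblast). For each list and contrast, the number of genes with a called event was compared with 10000 random gene sets matched on tested events per gene (one-sided permutation test, adjusted over 99 tests), and calls were also counted with p adjusted over the list alone. Event types were compared by Fisher's exact test, two-sided, adjusted over the 7 types; events of one gene are not independent, so these p-values are too small.

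The named genes were chosen as follows. For the SCR response and each shRNA effect without TGFβ, called events with all 3 libraries of one group above all 3 of the other were ranked by size, and the first 10 higher and 10 lower were taken, 1 per gene. The first 10 higher and 10 lower events called for both shRNAs were taken likewise, as were the first 5 higher and 5 lower interactions. From each list up to 4 genes with the largest called events were taken. Genes fixed in advance, among them HNRNPM, CD44, FGFR2, CTNND1, ENAH, SLK, EXOC7, PLEKHA1, NUMB, MAP3K7, FN1 and TCF7L2, were always included, each by its event with the most significant p. None of the 120 entries ranked this way, where an event can enter under more than 1 comparison, had a PSI between 0 and 1 in all 18 libraries. The same ranking was therefore repeated among the 21352 events (6978 genes) with a PSI strictly between 0 and 1 in all 18 libraries, called "read in every library" here; this filter was chosen after seeing the data. It leaves out events that a treatment switched fully on or off. Of the 120 entries it named, counted in the same way, 92 were also called over all 100288 events. Adjusted p-values are over all 100288 events unless stated.

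The response to TGFβ in the knockdown lines was set against that in SCR by the share of SCR events that fell under the 0.1 limit, by the same share with the lines exchanged, and by slopes. Overlaps of calls between comparisons that share control libraries were set beside 20 simulations of unchanged groups on the same controls and beside the overlap of independent lists. Simulated PSI was held within 0 and 1, which lowers its spread. Over all tested events these simulations understated the shared noise. The mean variance within the SCR groups (0.0261 untreated, 0.0271 with TGFβ), divided by 3 libraries, exceeds the simulated covariance. The simulated overlaps may be too low as well. After the data were seen, the covariance of these effects was also computed with the shared SCR libraries divided between them, 1 against 2. Skipped exons were matched to GENCODE v29 by gene identifier, exon length and flanking intron lengths, since v29 is on GRCh38 and no coordinate was converted: 143 of 165 named exons matched, of which 94 were coding, 11 partly coding, 12 untranslated and 26 present only in transcripts not typed as protein coding. After liver genes were found at 0 in some libraries, 5 marker lists (hepatocyte, resident macrophage and lymphocyte, gastrointestinal epithelium, lung epithelium, endothelium and fibroblast) were written, and the list genes with any PSI above 0 were counted in each library. All counts of genes with a PSI above 0 leave out retained intron events.

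The alternatives were PSI on a logit scale (held within 0.01 and 0.99), mean PSI between 0.05 and 0.95, size limits of 0.05 and 0.2, an adjusted p under 0.01, fits with the groups of one comparison alone, a variance prior without trend, a replicate block, unmatched gene sets, 1 event per gene and type, and leaving out each library. Alternatives with events read in every library, in at least 12 libraries, without the genes listed at 0, with corrected slopes, and with a library left out of the event type and list tests were chosen after seeing the data. Alternatives on missing values and on read numbers were not run, since nothing was missing and no read number is given. Annotation and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.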

Results

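Splicing was measured in 18 RNA sequencing libraries of A549 cells, a human lung adenocarcinoma line in which TGFβ induces an epithelial to mesenchymal transition (EMT). The cells carried a scrambled hairpin (SCR) or 1 of 2 hairpins against hnRNP M (sh1, sh2), an RNA-binding protein that regulates alternative splicing. They were left untreated or given TGFβ at 5 ng/ml for 72 h, with 3 libraries in each of the 6 groups. The measure was PSI, the share of a gene's transcripts that use a given exon, splice site, end or intron, deposited as a fraction from 0 to 1 for each library. The read number behind each value is unknown. PSI was above 0 for at least 1 event other than a retained intron in 12313 to 12602 genes per library. Libraries of the same group correlated across events at r = 0.846 to 0.865 (18 pairs) and libraries of different groups at r = 0.820 to 0.856 (135 pairs), where events are not independent replicates. The first principal component held 20.6% of the variance, the second 8.96% and the third 7.50%.

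The targeted gene came first. PSI does not give the level of HNRNPM, so the depth of knockdown was not measured here, and its 10 tested events include 7 with a mean PSI above 0.9. An intron of HNRNPM (chromosome 19, 8530246 to 8530364, hg19) was retained at 0.102 ± 0.054 (SD, n = 3) in untreated SCR cells, 0.242 ± 0.080 in untreated sh1 cells and 0.332 ± 0.074 in untreated sh2 cells. With TGFβ the values were 0.113 ± 0.0059 in SCR, 0.147 ± 0.055 in sh1 and 0.338 ± 0.041 in sh2. Retention rose in sh2 by 0.230 without TGFβ (limma adjusted p = 0.0299) and by 0.225 with TGFβ (adjusted p = 0.0441), whereas the sh1 difference of 0.140 did not pass (adjusted p = 0.264). That intron was the only HNRNPM event called in sh2. In sh1 limma called 0 HNRNPM events without TGFβ (smallest adjusted p = 0.101) and 0 with TGFβ (smallest adjusted p = 0.942).

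The first comparison asked how TGFβ changes splicing in cells with hnRNP M. TGFβ lowered inclusion of a 144 nt coding exon of NUMB, an endocytic adaptor that restrains Notch signalling (ENSG00000133961.15, chromosome 14, 73745989 to 73746132), from 0.553 ± 0.024 to 0.264 ± 0.049 (SD, n = 3 each; difference −0.289, SE 0.0321, limma adjusted p = 0.00101). An 81 nt coding exon of MAP3K7, the kinase TAK1 of the TGFβ pathway (ENSG00000135341.13, chromosome 6, 91254271 to 91254351), fell from 0.658 ± 0.0076 to 0.390 ± 0.053 (adjusted p = 0.0408), a call lost without any 1 of the 6 libraries (adjusted p 0.055 to 0.133). Retention of an intron of RGS2, a regulator of G protein signalling (ENSG00000116741.6, chromosome 1, 192779397 to 192779500), fell from 0.869 ± 0.035 to 0.384 ± 0.079 (adjusted p = 0.00106). Inclusion of a 24 nt coding exon of FLNA, an actin cross-linking filamin (chromosome X, 153585619 to 153585642), rose from 0.448 ± 0.013 to 0.670 ± 0.0083 (adjusted p = 0.00157). Retention of an intron of SMOX, the spermine oxidase (chromosome 20, 4162970 to 4163130), rose from 0.229 ± 0.023 to 0.586 ± 0.11 (adjusted p = 0.00651).

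Splicing regulators passed as a list in this comparison. Of 44 tested genes of the SR protein and splicing regulator list, 7 had a called event against 1.20 by chance (adjusted p = 0.00424; 8 genes adjusted over the list alone), and all 9 called events fell. A 104 nt exon of SRSF2 (chromosome 17, 74731854 to 74731957), an SR protein, fell from 0.476 ± 0.019 to 0.203 ± 0.020 (adjusted p = 0.000328); v29 holds this exon only in transcripts not typed as protein coding. A 73 nt exon of RBM39 (chromosome 20, 34328447 to 34328519), present only in transcripts typed as targets of nonsense-mediated decay, fell by 0.311 (adjusted p = 0.00387). The 54 nt exons of the muscleblind genes MBNL1 (chromosome 3, 152164493 to 152164546, coding) and MBNL2 (chromosome 13, 98009050 to 98009103) fell by 0.279 (adjusted p = 0.00167) and 0.302 (adjusted p = 0.0033). Of 25 hnRNP genes, HNRNPDL alone was called: a 105 nt exon found only in decay transcripts (ENSG00000152795.13, chromosome 4, 83346716 to 83346820) fell from 0.389 ± 0.035 to 0.0662 ± 0.014 (adjusted p = 1.9e-07). With events read in every library, 7 splicing regulators were again called but the list did not pass (adjusted p = 0.11).

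EMT genes were the other list to pass, with 8 of 46 tested genes called against 1.41 by chance (adjusted p = 0.0033; 14 adjusted over the list alone). Of their 9 called events, 3 rose and 6 fell. Beside NUMB and MBNL1, a 57 nt coding exon of CLSTN1, a calsyntenin that binds kinesin (chromosome 1, 9797556 to 9797612), rose by 0.223 (adjusted p = 0.00352). An exon of CD44, the hyaluronan receptor (chromosome 11, 35223218 to 35223334), was listed at 0 in each untreated and at 1 in each treated SCR library. That CD44 event was not called without any 1 of the 6 libraries (adjusted p 0.0815 to 0.0923). With the replicate block the list did not pass. Without any 1 of 4 libraries, 4 EMT genes were called and the list no longer passed. The adjusted p was 0.181 without SCR untreated replicate 1, 0.155 without SCR untreated replicate 2, 0.0965 without SCR TGFβ replicate 1 and 0.12 without SCR TGFβ replicate 3. In the actin list, 4 of 45 genes were called (adjusted p = 0.155; 11 adjusted over the list alone). Among them was the tropomyosin gene TPM1, where PSI of an alternative first exon event (chromosome 15, 63336351 to 63349184) fell from 0.349 ± 0.0096 to 0.0730 ± 0.017 (adjusted p = 1.99e-08). The vesicle list had 4 of 42 genes called (adjusted p = 0.0942; 8 adjusted over the list alone), with all 5 events lower, among them EXOC1 of the exocyst (−0.225). In the TGFβ and SMAD list 3 of 42 genes were called (adjusted p = 0.205; 5 adjusted over the list alone), among them MAP3K7 and PMEPA1 (−0.226). With any 1 library left out, 1 gene of that list was called. With events read in every library, the actin list passed with 8 genes (adjusted p = 0.00636) and the vesicle list with 6 (0.0461).

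The remaining lists did not pass in the SCR response over all tested events, whereas the matrix list passed with events read in every library (4 genes, adjusted p = 0.0461). Called genes numbered 2 of 35 for cell adhesion (adjusted p = 0.573; 2 adjusted over the list alone), 2 of 32 for extracellular matrix (adjusted p = 0.28; 3 adjusted over the list alone), 1 of 46 for cell cycle and DNA repair and 1 of 25 for the hnRNP family (adjusted p = 0.845). The matrix genes included PLOD2, a collagen lysyl hydroxylase (0.137), which was not called without SCR TGFβ replicate 1 (adjusted p = 0.0614) or replicate 2 (0.0564). None of 23 apoptosis genes and none of 15 tested markers of other cell types was called by limma. At unadjusted p under 0.05, 7881 events of any gene passed. Several genes named in advance were not called: FGFR2 (0.333, adjusted p = 0.695), ENAH (0.0300, 0.651), SLK (−0.0739, 0.804), EXOC7 (0.156, 0.308), FN1 (0.111, 0.117) and TCF7L2 (0.119, 0.695). For CTNND1, p120 catenin, the difference of −0.0382 lay under the size limit (adjusted p = 0.00679).

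In all, limma called 323 events of 263 genes in SCR, of which 105 rose and 218 fell. All 323 separated the 3 treated from the 3 untreated libraries fully, as 10% of events would by chance, and 14 had values of 0 or 1 alone. Among called events 60 were retained introns (odds ratio 3.22, Fisher's exact adjusted p = 3.7e-12), while 126 were skipped exons (odds ratio 0.701, adjusted p = 0.00411). Among events read in every library, the log2 odds ratio of skipped exons turned from −0.51 to 0.19 (adjusted p = 0.216), and with 1 event per gene and type it turned to 0.47 (adjusted p = 0.0148). It did not pass with a mean PSI between 0.05 and 0.95 (−0.22, adjusted p = 0.362), without SCR TGFβ replicate 1 (−0.15, 0.482) or without SCR TGFβ replicate 3 (−0.33, 0.128). Events read in every library gave 493 calls. A fit of the SCR groups alone ended the calls of NUMB (adjusted p = 0.0781), RGS2 (0.0669), SMOX (0.217), MBNL1 (0.0509), RBM39 (0.0622) and MBNL2 (0.0619).

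**Figure D1:**
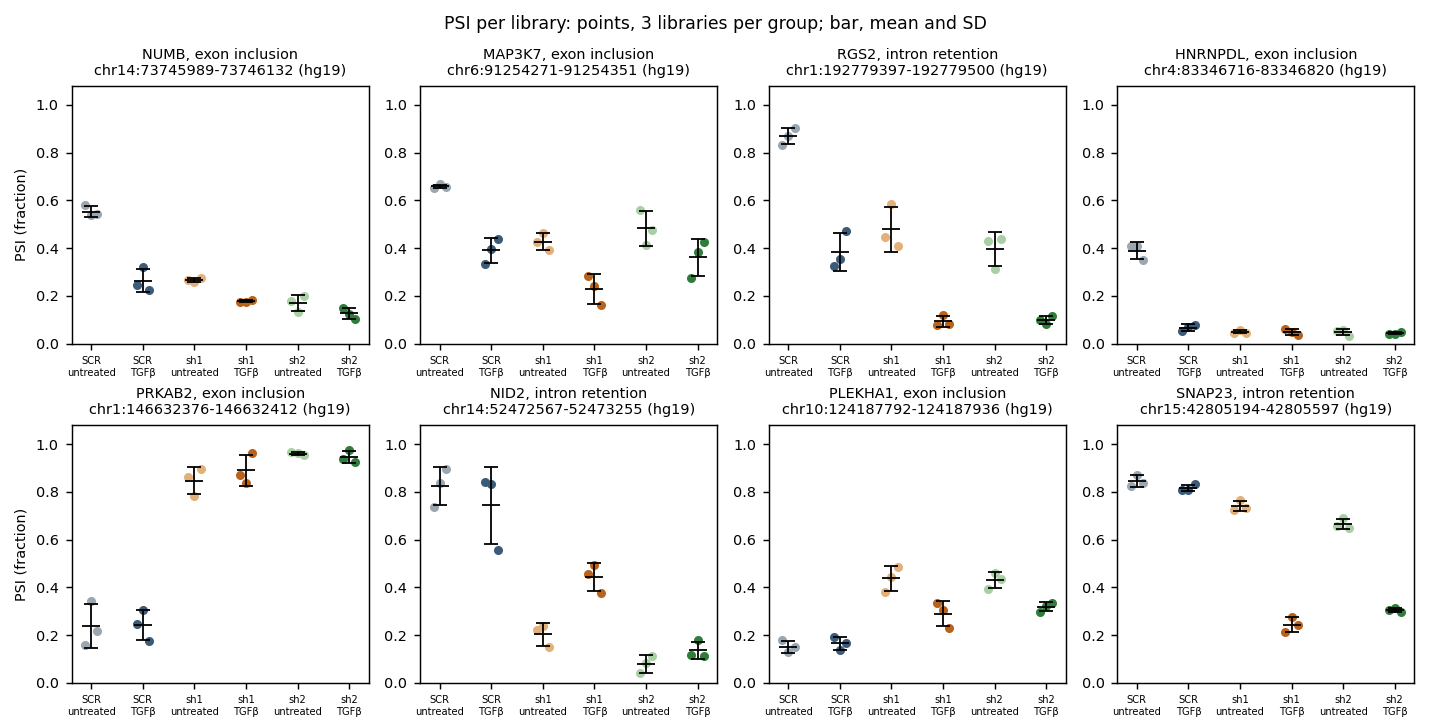
PSI (fraction from 0 to 1, vertical axis) of events in NUMB, MAP3K7, RGS2, HNRNPDL, PRKAB2, NID2, PLEKHA1 and SNAP23 in the 6 groups (horizontal axis); points are the 3 libraries of a group, and bars show their mean and SD. The NUMB exon has a mean of 0.553 in untreated SCR cells and of 0.265 or lower in each other group, while SNAP23 is lowest in the knockdown lines with TGFβ (0.244 and 0.305).

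The effect of hnRNP M knockdown without TGFβ was compared for each hairpin with untreated SCR cells. Inclusion of a 37 nt exon of PRKAB2, a subunit of the kinase AMPK (ENSG00000131791.6, chromosome 1, 146632376 to 146632412, in a transcript not typed as protein coding), rose from 0.240 ± 0.093 to 0.847 ± 0.057 in sh1 (SD, n = 3; adjusted p = 6.58e-05) and to 0.960 ± 0.0069 in sh2 (adjusted p = 9.36e-06). Retention of an intron of NID2, a basement membrane nidogen (ENSG00000087303.12, chromosome 14, 52472567 to 52473255), fell from 0.824 ± 0.080 to 0.203 ± 0.048 in sh1 (adjusted p = 0.000681) and 0.0789 ± 0.037 in sh2 (adjusted p = 0.000111). An 84 nt coding exon of GPR126, an adhesion G protein-coupled receptor (chromosome 6, 142704897 to 142704980), fell from 0.921 ± 0.017 to 0.506 ± 0.011 in sh1 (adjusted p = 3.4e-05) and 0.493 ± 0.046 in sh2 (adjusted p = 1.72e-05). An 88 nt untranslated exon of ATM, the DNA damage kinase (ENSG00000149311.13, chromosome 11, 108095511 to 108095598), rose from 0.274 ± 0.075 to 0.770 ± 0.078 in sh1 (adjusted p = 0.00476) and 0.882 ± 0.049 in sh2 (adjusted p = 0.000785).

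Other events called for both hairpins included a 96 nt coding exon of ADD3, an adducin of the membrane skeleton (chromosome 10, 111892063 to 111892158; −0.392 in sh1 and −0.398 in sh2), a retained intron of IL18BP, the interleukin 18 binding protein (0.719 and 0.391), and a first exon event of SETD5 (0.476 and 0.475). A 145 nt exon of PLEKHA1, partly coding (ENSG00000107679.10, chromosome 10, 124187792 to 124187936), rose from 0.152 ± 0.025 to 0.437 ± 0.054 in sh1 (adjusted p = 0.00235) and 0.430 ± 0.034 in sh2 (adjusted p = 0.00182). The NUMB exon fell to 0.265 ± 0.0086 in sh1 (adjusted p = 0.000638) and 0.170 ± 0.034 in sh2 (adjusted p = 4.13e-05). A fit of the 2 groups alone ended the sh1 calls of ATM (adjusted p = 0.0712) and PLEKHA1 (0.0652).

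The EMT list passed for both hairpins: 16 of 46 genes in sh1 against 3.12 by chance (adjusted p = 0.00247, the smallest adjusted value here; 23 adjusted over the list alone) and 22 in sh2 against 5.17 (adjusted p = 0.00247; 25 adjusted over the list alone). More of their called events rose than fell, 20 against 12 in sh1 and 26 against 14 in sh2. The CLSTN1 exon rose by 0.377 in sh1 (adjusted p = 3.4e-05) and 0.411 in sh2 (adjusted p = 1.01e-05).

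Splicing regulators passed for both hairpins. Of 44 genes, 10 were called in sh1 against 2.77 by chance (adjusted p = 0.0033; 14 adjusted over the list alone; 2 events higher, 14 lower) and 12 in sh2 against 4.41 (adjusted p = 0.00577; 13 adjusted over the list alone; 5 higher, 18 lower). SRSF2 fell by 0.319 in sh1 and 0.327 in sh2, and MBNL1 by 0.309 and 0.429. The list did not pass in sh1 without SCR untreated replicate 2 (7 genes, adjusted p = 0.0549) or sh1 untreated replicate 3 (7 genes, 0.0538), nor in sh2 among events read in every library (14 genes, adjusted p = 0.177). In the hnRNP list 2 of 25 genes were called in sh1 (adjusted p = 0.809) and 5 in sh2 (adjusted p = 0.331; 8 adjusted over the list alone), and in each the HNRNPDL exon fell, by 0.340 (adjusted p = 9.85e-08) and 0.342 (adjusted p = 6.76e-08).

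The actin list passed in both, with 10 genes in sh1 against 3.28 by chance (adjusted p = 0.00919; 12 adjusted over the list alone) and 13 in sh2 against 5.23 (adjusted p = 0.00577; 16 adjusted over the list alone). A 36 nt coding exon of LIMCH1, an actomyosin regulator (chromosome 4, 41640949 to 41640984), rose by 0.442 (adjusted p = 0.000201) and 0.457 (adjusted p = 9.59e-05), and the TPM1 first exon event fell by 0.270 and 0.289. In sh2 the actin list did not pass without SCR untreated replicate 1 (9 genes, adjusted p = 0.112) or replicate 2 (10 genes, 0.0549), without sh2 untreated replicate 3 (9 genes, 0.0613), or among events read in every library (12 genes, 0.114).

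In the vesicle list, 7 genes were called in sh1 (adjusted p = 0.0688; 9 adjusted over the list alone), with all 10 called events lower, and 12 in sh2 against 4.26 by chance (adjusted p = 0.00577; 13 adjusted over the list alone; 1 event higher, 16 lower). An exon of PICALM, a clathrin assembly protein, fell in sh2 by 0.257 (adjusted p = 0.000409). The sh1 list passed without sh1 untreated replicate 2 (7 genes, adjusted p = 0.0396) and among events read in every library (12 genes, 0.00757), and the sh2 list did not pass without SCR untreated replicate 2 (8 genes, 0.0839) or among events read in every library (11 genes, 0.0848).

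The extracellular matrix list passed in sh2, with 8 of 32 genes against 2.00 by chance (adjusted p = 0.00577; 11 adjusted over the list alone), and not in sh1 (4 genes, adjusted p = 0.113; 4 adjusted over the list alone). It did not pass in sh2 without SCR untreated replicate 1 (5 genes, adjusted p = 0.112) or replicate 2 (5 genes, 0.0916), or without sh2 untreated replicate 1 (4 genes, 0.248) or replicate 2 (5 genes, 0.0748). Adhesion genes numbered 6 of 35 in sh1 (adjusted p = 0.113) and 8 in sh2 (adjusted p = 0.118; 0.00247 with 10 genes without sh2 untreated replicate 2). With 1 library left out, sh1 had 1 to 4 matrix genes and 3 to 6 adhesion genes called. Cell cycle genes numbered 4 and 6 of 46 (adjusted p = 0.679 and 0.692), TGFβ and SMAD genes 2 and 5 of 42 (0.912 and 0.554), and apoptosis genes 1 of 23 in each. Limma called 0 of the 15 markers of other cell types in either hairpin, where 10419 events of any gene in sh1 and 11397 in sh2 had an unadjusted p under 0.05.

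Limma called 782 events of 579 genes in sh1 (349 higher, 433 lower) and 1315 events of 935 genes in sh2 (618 higher, 697 lower), and events read in every library gave 1271 and 1797. Retained introns were over-represented, with 126 in sh1 (odds ratio 2.73, Fisher's exact adjusted p = 3.5e-19), of which 82 rose and 44 fell, and 219 in sh2 (odds ratio 2.86, adjusted p = 4.7e-35), of which 110 rose and 109 fell. Among events read in every library the odds ratios were 1.70 (adjusted p = 1.13e-11) and 1.62 (adjusted p = 8.07e-13). Between hairpins, 559 events were called in the same direction, 254 higher and 305 lower, and 0 in opposite directions. Independent lists would share 2.15 higher and 3.01 lower, and at most 7 were shared in 20 simulations of unchanged groups on the same SCR libraries. The covariance of the effects was 0.0139 against a simulated 0.00623, which understates the shared noise. With the 3 SCR libraries divided between the hairpins, a choice made after seeing the data, the covariance was 0.00521 (0.00501 to 0.00561 over 6 divisions). A difference common to all 3 SCR libraries would stay in it.

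The same hairpins were compared with SCR cells under TGFβ. Retention of an intron of SNAP23, a SNARE protein of membrane fusion (ENSG00000092531.5, chromosome 15, 42805194 to 42805597), was lower in knockdown cells, at 0.244 ± 0.032 in sh1 and 0.305 ± 0.0075 in sh2 against 0.815 ± 0.014 in SCR (SD, n = 3; adjusted p = 6.85e-08 and 2.54e-07). The PRKAB2 exon was higher by 0.647 in sh1 (adjusted p = 8.43e-06) and 0.704 in sh2 (adjusted p = 3.18e-06), and the LIMCH1 exon by 0.350 and 0.287. An 87 nt exon of NFYA, a subunit of the transcription factor NF-Y (chromosome 6, 41048550 to 41048636), was higher by 0.299 (adjusted p = 0.0097) and 0.314 (adjusted p = 0.00546). The GPR126 exon differed by −0.288 and −0.261, and an exon of ENAH, an actin regulator (chromosome 1, 225704898 to 225705008), by −0.115 and −0.113. The NID2 intron was lower in sh2 (−0.607, adjusted p = 0.00043), while the sh1 difference of −0.300 did not pass (adjusted p = 0.082). A 273 nt coding exon of FN1, the matrix protein fibronectin (chromosome 2, 216257654 to 216257926), differed by −0.101 (adjusted p = 0.0426) and −0.156 (adjusted p = 0.00161).

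The EMT list passed with 10 genes in sh1 against 2.18 by chance (adjusted p = 0.00247; 17 adjusted over the list alone) and 12 in sh2 against 3.36 (adjusted p = 0.00495; 23 adjusted over the list alone). Actin genes numbered 7 in sh1 (adjusted p = 0.0473; 9 adjusted over the list alone) and 9 in sh2 (adjusted p = 0.0297; 12 adjusted over the list alone). Matrix genes numbered 3 in sh1 (adjusted p = 0.205) and 6 in sh2 (adjusted p = 0.00924; 7 adjusted over the list alone). In the other lists the counts for sh1 and sh2 were 1 and 3 hnRNP genes, 2 and 4 splicing regulators, 2 and 4 adhesion genes and 3 and 4 vesicle genes. There were 2 and 5 cell cycle genes, 2 and 0 apoptosis genes and 0 and 0 TGFβ and SMAD genes, and none of these lists passed over all tested events. With events read in every library, the adhesion list passed with 10 genes in sh1 (adjusted p = 0.0009, the smallest adjusted value in that set) and 10 in sh2 (0.0302), and the matrix list passed in sh1 too (5 genes, 0.0154). Limma called 679 events of 470 genes in sh1 (296 higher, 383 lower) and 948 events of 658 genes in sh2 (499 higher, 449 lower), with 9057 and 9752 events at an unadjusted p under 0.05. The hairpins shared 445 events in the same direction (267 without the genes listed at 0, described next) and 1 in the opposite one, against 1.47 higher and 1.71 lower for independent lists and at most 9 in simulations on the shared SCR libraries. The covariance was 0.0156 against a simulated 0.00627, and 0.00654 (0.00604 to 0.00692) with the SCR libraries divided between the hairpins.

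Events of many genes of other tissues were listed at 0 in the knockdown libraries with TGFβ. In all 6 knockdown libraries with TGFβ, 212 events of 116 genes were listed at 0 while the mean of each of the other 4 groups was over 0.5. No other pair of the 6 groups had more than 9 such events. The 116 genes included the plasma protein genes ALB, APOA1, APOA2, HP, CRP, TF and PLG, the cytochrome gene CYP2E1, and the intestinal genes VIL1, TFF2 and CEACAM5. A PSI of 0 does not show that a gene was not read, since retained intron events of USF2, NACA and PIGC, which are not genes of one tissue, were also among the 212. Retained introns were left out of the following counts. Of 36 hepatocyte list genes with a PSI above 0 in some library, 14 to 16 had one in each of the 6 libraries and 32 to 36 in each of the other 12. Gastrointestinal list genes numbered 5 to 8 of 10 in the 6 libraries and 9 to 10 in the others, and macrophage and lymphocyte genes 14 to 17 of 21 and 9 to 16. Lung epithelium genes numbered 3 to 4 of 6 in both, and endothelium and fibroblast genes 3 to 7 of 12 and 4 to 8. Without these 116 genes, 442 events were called in sh1 and 738 in sh2, and lower events fell from 383 to 195 and from 449 to 270. Exons of PTPRC and MS4A1, genes of lymphocytes, were listed at 0 in the 12 other libraries. With TGFβ, PTPRC stood at 1, 0.556 and 1 in sh1 and 0.467, 1 and 1 in sh2, and MS4A1 at 1, 0.333 and 1 in sh1 and at 1 in each sh2 library. Thus 2 of 15 markers of other cell types were called in each line (adjusted p = 0.113 and 0.118).

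**Figure D2:**
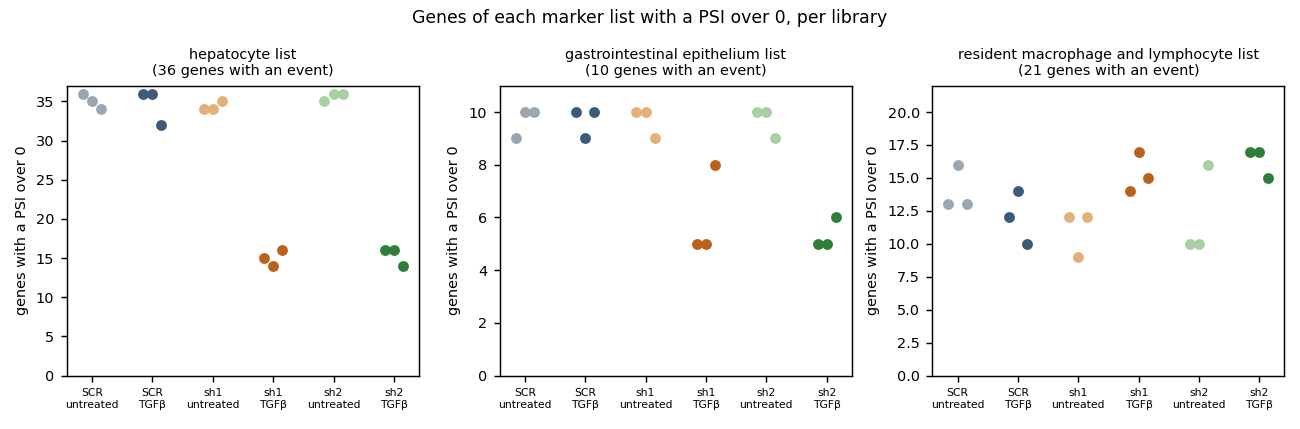
Number of marker genes with a PSI above 0 outside retained introns (vertical axis, genes per library) in the hepatocyte, gastrointestinal epithelium and macrophage and lymphocyte lists for the 6 groups (horizontal axis). Each point is 1 library. The 6 knockdown libraries with TGFβ lie at 14 to 16 hepatocyte genes and the other 12 at 32 to 36.

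The TGFβ response was then measured within each knockdown line. The FLNA exon rose in both, by 0.219 in sh1 (adjusted p = 0.000752) and 0.173 in sh2 (adjusted p = 0.0074), and the RGS2 intron fell by 0.386 in sh1 (adjusted p = 0.00332) and 0.295 in sh2 (adjusted p = 0.0334). The SNAP23 intron fell from 0.740 ± 0.022 to 0.244 ± 0.032 in sh1 (adjusted p = 3.7e-07) and from 0.665 ± 0.022 to 0.305 ± 0.0075 in sh2 (adjusted p = 1.68e-05). A 240 nt coding exon of TJP1, the tight junction protein ZO-1 (chromosome 15, 30011981 to 30012220), fell by 0.335 in sh1 (adjusted p = 6.74e-05) and 0.202 in sh2 (adjusted p = 0.0101). A 36 nt coding exon of MBNL1 (chromosome 3, 152173331 to 152173366) rose by 0.222 (adjusted p = 0.000617) and 0.180 (adjusted p = 0.00502).

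EMT genes with a call numbered 5 in sh1 against 1.37 by chance (adjusted p = 0.0531; 9 adjusted over the list alone) and 5 in sh2 against 1.20 (adjusted p = 0.046; 6 adjusted over the list alone). Actin genes numbered 5 and 4 (adjusted p = 0.0574 and 0.113), adhesion genes 3 and 2, vesicle genes 2 and 1, and splicing regulators 1 and 2. Markers of other cell types numbered 2 in each (adjusted p = 0.0829 and 0.0775), PTPRC and MS4A1. Limma called 0 genes in either line for the hnRNP family, cell cycle and apoptosis. It called 0 in sh1 and 1 in sh2 for each of the TGFβ and SMAD and matrix lists, with 7903 and 6746 events at an unadjusted p under 0.05. With events read in every library, the EMT list passed in sh1 too (10 genes, adjusted p = 0.0009), the actin list in both lines (9 and 7 genes, 0.0009 each), and the adhesion (5 genes, 0.0428) and matrix (3 genes, 0.0482) lists in sh1. In all, 484 events of 327 genes were called in sh1 (123 higher, 361 lower) and 400 events of 285 genes in sh2 (123 higher, 277 lower). Without the genes listed at 0 the counts were 270 (107 higher, 163 lower) and 153 (84 higher, 69 lower), and among events read in every library 261 and 182. Retained introns made up 111 and 84 of the calls (odds ratios 4.23 and 3.76; 6.58 and 4.64 among events read in every library).

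Whether knockdown altered the TGFβ response was tested by the interaction. The HNRNPDL exon, which fell with TGFβ in SCR cells, stood at 0.0489 ± 0.0064 and 0.0488 ± 0.012 without and with TGFβ in sh1 and at 0.0472 ± 0.012 and 0.0441 ± 0.0050 in sh2 (SD, n = 3; interaction 0.323, adjusted p = 1.51e-06, and 0.320, adjusted p = 1.68e-06). The SRSF2 exon gave interactions of 0.296 (adjusted p = 0.00162) and 0.288 (adjusted p = 0.00222) in the same way. Both exons had already fallen in untreated knockdown cells, HNRNPDL to near 0, which left it little room to fall with TGFβ. For HNRNPDL the interaction cannot tell an altered TGFβ response from this limit. The SNAP23 intron showed the opposite order. It differed by −0.0284 with TGFβ in SCR (adjusted p = 0.933) and fell in the knockdown lines (interaction −0.468, adjusted p = 4.43e-05, and −0.331, adjusted p = 0.00177). Retention of an intron of BCL2, the apoptosis inhibitor (ENSG00000171791.10, chromosome 18, 60986185 to 60986407), fell from 0.820 to 0.132 in sh1 and from 0.709 to 0.152 in sh2, against 0.846 to 0.750 in SCR (interaction −0.592, adjusted p = 0.00215, and −0.462, adjusted p = 0.0189; 0.0519 without sh2 untreated replicate 1, 0.0994 on the logit scale and 0.0869 with only the compared groups fitted). The MBNL1 exon of 36 nt gave 0.266 (adjusted p = 0.0037) and 0.225 (adjusted p = 0.0162). For FLNA, with interactions of −0.00314 and −0.0488, no difference between lines was called. The TGFβ responses of sh1 and sh2, which share no library, correlated at 0.916 with noise removed (0.875 without the genes listed at 0). Their correlations with the SCR response were 0.393 and 0.303. SNAP23 and BCL2 fell in the same 6 libraries in which the 116 genes were listed at 0. A difference of these libraries as a set cannot be told apart from a changed TGFβ response.

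Splicing regulators passed in the sh1 interaction, with 5 genes against 0.827 by chance (adjusted p = 0.00609; 6 adjusted over the list alone) and all 8 events higher. In sh2 there were 3 genes (adjusted p = 0.155; 8 adjusted over the list alone) with all 5 events higher. EMT genes numbered 7 in sh1 (adjusted p = 0.00247; 10 adjusted over the list alone) and 3 in sh2 (adjusted p = 0.165; 7 adjusted over the list alone). Actin genes numbered 4 and 3 (adjusted p = 0.0636 and 0.155). For NUMB the interaction was 0.201 in sh1 (adjusted p = 0.124) and 0.246 in sh2 (adjusted p = 0.0377). The sh2 call of NUMB was lost without SCR untreated replicate 1 (adjusted p = 0.0708) or 3 (0.0507), SCR TGFβ replicate 1 (0.0827) or 3 (0.0707), sh2 untreated replicate 1 (0.0673) or 2 (0.0822), and sh2 TGFβ replicate 1 (0.0847) or 2 (0.0741). The remaining lists had at most 2 called genes in either interaction, and none passed over all tested events. With events read in every library, the sh2 interaction passed for EMT genes (8 genes, adjusted p = 0.0009) and splicing regulators (6 genes, 0.00577), and the sh1 interaction for actin (4 genes, 0.043) and vesicle genes (4 genes, 0.0461).

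Each interaction gave 289 called events, 87 higher and 202 lower in sh1 and 109 higher and 180 lower in sh2, of which 200 were shared in direction and 0 opposed (84 shared among events read in every library, 69 without the genes listed at 0). Independent lists would share 0.0946 higher and 0.363 lower, and simulations on the shared SCR libraries gave at most 8 (covariance 0.0236 against 0.0125, and 0.00587 with the SCR libraries divided, lowest 0.00436 and highest 0.00687 of 36 divisions). The direction depended on the events used. Of the calls, 69.9% in sh1 and 62.3% in sh2 were lower over all events, against 42.2% of 204 and 35.5% of 152 calls among events read in every library. Without the genes listed at 0, the counts were 117 and 139. Of the 323 events called in SCR, the interaction was called for 69 in sh1 and 79 in sh2, all toward a smaller response, while 25 and 19 were called in the same direction in the knockdown line. Choosing events by their response favours that direction: of the 484 events called in sh1 and 400 in sh2, the interaction was called for 203 and 188, all with the smaller response in SCR. These counts depend on the events used: among events read in every library they were 68 of 261 (66 with the smaller response in SCR) and 42 of 182 (42), against 98 (96 toward a smaller response) and 92 (90) of the 493 called in SCR. The untreated knockdown effect was called in the direction of the SCR response for 194 (sh1) and 210 (sh2) of the 323. Independent lists would share 0.365 higher and 0.941 lower with sh1 and 0.647 and 1.52 with sh2, and simulations gave at most 7 and 8. The covariances were 0.0113 against a simulated 0.00626 and 0.0115 against 0.00622, where the simulated values understate the shared noise. With the 3 untreated SCR libraries divided between the compared effects, they were 0.00263 (0.00237 to 0.00292) and 0.00283 (0.00256 to 0.00320).

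**Figure D3:**
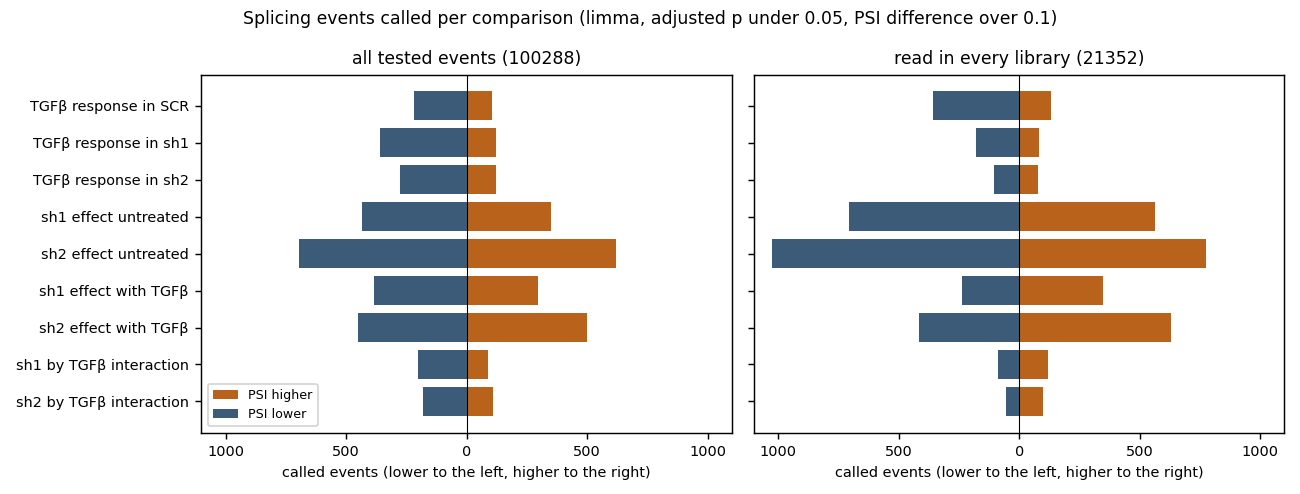
Number of events called by limma (horizontal axis, lower to the left and higher to the right) in each of the 9 comparisons (vertical axis), over all 100288 tested events and over the 21352 read in every library; bars are counts with no error. The TGFβ response in SCR has 323 calls over all events and 493 among those read in every library.

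Finally, responsive events were counted by size alone, as in the series' design text. In SCR 19465 events differed by over 0.1 with TGFβ (19513 before repeated events were removed), whereas the design text gives 13726. Of the 19465, 47.5% fell under 0.1 in sh1, 48.1% in sh2 and 28.6% in both. When the lines were exchanged, 49.8% of events chosen in sh1 and 48.4% of those chosen in sh2 fell under 0.1 in SCR. Among limma calls the shares were 66.9% (sh1) and 72.4% (sh2), against 68.0% and 66.5% exchanged. By size among events read in every library they were 69.9% and 72.1%, against 65.8% and 65.1%, and among limma calls in that set 76.1% and 80.5%, against 60.2% and 64.3%. The slope of the knockdown response on the SCR response, with events chosen and measured in different SCR libraries, was 0.0356 in sh1 (range 0.0284 to 0.0460) and 0.0274 in sh2 (0.0200 to 0.0413). With 1 library left out, this slope was 0.0246 to 0.0381 in sh1 and 0.0147 to 0.0311 in sh2. Noise made up 85.7% of the SCR differences' sum of squares. With that noise removed, a choice made after seeing the data, the slopes were 0.599 (0.378 to 0.787 with 1 library left out) and 0.437 (0.218 to 0.599). Among events read in every library, noise made up 52.3% and the slopes were 0.314 (0.291 to 0.349) and 0.247 (0.228 to 0.268).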

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

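The test on exchanged lines and the tests on reads or loss of liver genes were chosen after the result was seen, as were the fits on events read in every library and the noise-corrected slopes. What singled out the results in this part was the interaction test, which compares the TGFβ response of a knockdown line with that of SCR. It called 289 events in sh1 and 289 in sh2.

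Many of the largest differences came from events listed at 0 or 1. In sh1 and sh2 the response differed by 1.94 and 1.56 for the exon of the transporter gene SLC6A13 and by 1.56 and 1.67 for the 5' splice site of BIN2. It differed by 1 in each line for CATSPERB, by 1 in each for MYO7B and by 1 in each for ZNF707. The opposite direction held SHBG (−1.68 and −1.68), EBNA1BP2 (−1.67 and −1.67), DAO (−1.67 and −1.67), SLC7A7 (−1.17 and −1.17) and COLEC11 (−1.13 and −1.13). None of these 10 events lay between 0 and 1 in all 18 libraries.

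Of the events read in every library, the HNRNPDL exon, near 0 already in untreated knockdown cells, differed by 0.323 in sh1 and 0.320 in sh2. An intron of the guanine nucleotide exchange factor PREX1 differed by 0.297 (adjusted p = 0.00763) and 0.366 (adjusted p = 0.0011). The first exon event of FGD4 differed by 0.414 (adjusted p = 0.128) and 0.549 (adjusted p = 0.0215), the ABCF3 intron by 0.309 (adjusted p = 0.0433) and 0.311 (adjusted p = 0.0403), and the exon of SAT1, a polyamine acetyltransferase, by 0.305 (adjusted p = 0.0704) and 0.342 (adjusted p = 0.0331). With 1 library left out, the FGD4 call in sh2 was lost without sh2 untreated replicate 1 (0.0586) or 2 (0.0569) or sh2 TGFβ replicate 2 (0.0557). The ABCF3 call was lost in sh1 without any library but sh1 TGFβ replicate 3 (0.0506 to 0.0899) and in sh2 without any but sh2 TGFβ replicate 1 (0.0521 to 0.0986). The SAT1 call in sh2 was lost without any library but sh2 untreated replicate 2, SCR TGFβ replicates 2 and 3 and sh2 TGFβ replicate 1 (0.0534 to 0.0803). Lower values were found for an exon of the plasma protein gene ITIH4 (−0.485 and −0.561), the introns of BCL2 (−0.592 and −0.462), SNAP23 (−0.468 and −0.331) and SMOX, a polyamine oxidase (−0.429 and −0.363), and the first exon event of SREBF1, a regulator of lipid synthesis (−0.367 and −0.330). The SMOX value passed in sh1 (adjusted p = 0.0207) and not in sh2 (adjusted p = 0.0653), and the sh1 call was lost without sh1 untreated replicate 1 (adjusted p = 0.0572).

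Of 36 hepatocyte genes, 14 to 16 had a PSI above 0 outside retained introns in the 6 knockdown libraries with TGFβ and 32 to 36 in the other 12. The median number of all genes with such a PSI in the 6 libraries lay 0.464% below that of the 12. That number differed little between any libraries (12313 to 12602), so it cannot exclude a lower depth at weakly read genes. Pairs of skipped exon events that mark unread events, described above, numbered 273 to 390 (median 314) in the 6. In the 12 they numbered 194 to 321 (median 239.5). Reads of whole liver tissue in the 12 libraries would also bring macrophage and lymphocyte genes, but their median was 16 in the 6 libraries and 12 in the 12. Since up to 17 of these 21 genes have a PSI above 0 in the 6, this does not decide against a small share of liver reads. Nor can it bear on reads of liver or gut cells free of immune cells. Loss of liver genes by the cells may also hold, but the gastrointestinal list fell in the same libraries. The group and the order of the library names cannot be told apart, and lower depth, liver reads and loss of liver genes stay open.

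Of the events that TGFβ moved by over 0.1 in SCR, 47.5% in sh1 and 48.1% in sh2 fell under that limit. Choosing events on a noisy difference stays open there: the exchanged minus the observed share was 2.25 points in sh1 and 0.35 in sh2, and among events read in every library −4.08 (−8.30 to 1.41 with 1 library left out) and −6.98 (−11.2 to −2.06). For limma calls over all events it stays open too (1.10 and −5.95). For limma calls read in every library the value was −15.9 (−21.4 to −8.82) and −16.2 (−23.2 to −12.2). This cannot exclude it as the whole source, since the filter drops events that reach 0 or 1 in the knockdown lines. The set also held 493 calls in SCR against 261 in sh1 and 182 in sh2. Within groups of that set the SCR libraries did not vary more (mean variance 0.00409 and 0.00410) than the knockdown libraries (0.00434 to 0.00479). A weaker response of the same events may contribute, with noise-corrected slopes of 0.599 and 0.437, but those of SCR on the knockdown lines were lower (0.257 and 0.210) and, among events read in every library, higher (0.445 and 0.447 against 0.314 and 0.247), so that the slopes do not show which line responds less.

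Knockdown without TGFβ moved events the way TGFβ moved them in SCR. Noise of the shared untreated SCR libraries was excluded as the whole source, since the noise-corrected slopes stayed above 0 with any library left out, at least 0.797 in sh1 and 0.881 in sh2 over all tested events and 0.791 and 0.877 without the genes listed at 0. Untreated SCR libraries that stand apart for a technical reason, and a shift of the knockdown cells along the TGFβ response, cannot be told apart. Between comparisons with no library in common, the correlation was 0.0193 (0.00291 to 0.0326 with 1 library left out) for the sh1 effect with the sh2 response and 0.117 (0.100 to 0.144) for the sh2 effect with the sh1 response. The rule asked for both above 0.1 or both at or below 0, and only the second value lies above 0.1. Low values could not have decided against a shift. Events that had already moved in untreated knockdown cells, such as the HNRNPDL exon, may not respond further to TGFβ.

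With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10 splits, the real one, reached the real count. The real count and the highest other were 323 and 29 for TGFβ in SCR, 484 and 20 in sh1, and 400 and 19 in sh2. For knockdown they were 782 and 24 for sh1 untreated, 1315 and 22 for sh2 untreated, 679 and 23 for sh1 with TGFβ, and 948 and 22 for sh2 with TGFβ. For the interactions, counted with the average hairpin effect removed first, 1 of 50 drawn splits reached the real count (289 against at most 28 in sh1, 292 against at most 20 in sh2). A chance assignment of these libraries to groups can be excluded there. The splits do not test chance differences between cultures or preparations, since the libraries of a group may be technical replicates.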

How the results depend on the processing

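Alternatives with events read in every library, in at least 12 libraries or without the genes listed at 0, the corrected slopes, and leaving a library out of the event type and list tests were chosen after seeing the data. Named events are counted here once per comparison. Alternatives chosen before the data were seen and run on named events were the logit scale, no trend, the replicate block, the compared groups alone and each library left out. The other size limits, the adjusted p under 0.01 and the filter on mean PSI were not applied to named events. Of 285 called named events, 150 kept direction and call in every alternative run on them. Of the 285, 135 lost the call in any of these, and 195 kept it with each library left out. The call was lost for 24 on the logit scale, 39 with the replicate block and 87 with only the compared groups fitted. Of 105 uncalled named events read in every library, 70 were called when those events were fitted alone. A stricter limit lowers counts by construction, and otherwise the cause was not tested. Read depth is not given, so what depth limits is unknown, and the alternatives on missing values and read numbers were not run.

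An adjusted p under 0.01 left 129, 269 and 224 events for TGFβ in SCR, sh1 and sh2, 344 and 573 for sh1 and sh2 untreated, 328 and 448 with TGFβ, and 188 and 190 for the interactions. A size over 0.2 left 196 for TGFβ in SCR, 467 and 815 for sh1 and sh2 untreated and an overlap of 316. By size alone it gave 10851 events, shares of 55.9%, 56.3% and 36.3% (sh1, sh2, both) and exchanged shares of 60.3% and 58.4%. A size over 0.05 gave 30238 events, 40.0%, 40.9% and 22.1%, exchanged 41.5% and 40.4%. It gave 6 actin genes in SCR (adjusted p = 0.0346) and 6 matrix genes in sh1 untreated (adjusted p = 0.0183). With only the compared groups sh2 untreated had 779, and without trend SCR had 492.

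Events read in every library gave 493, 261 and 182 calls for TGFβ in SCR, sh1 and sh2, 1271 for sh1 untreated, 152 for the sh2 interaction, and overlaps of 856 (untreated) and 84 (interaction). By size alone they gave 2907 events, 69.9%, 72.1% and 54.5%, exchanged 65.8% and 65.1%, and slopes of 0.108 and 0.0938. Over all events the instrumental slopes were 0.576 and 0.414 and the noise-corrected ones 0.599 and 0.437. In at least 12 libraries the counts were 249 and 185 for TGFβ in sh1 and sh2, 148 and 150 for the interactions and 73 shared. Without the genes listed at 0 they were 270 and 153, 442 for sh1 with TGFβ, 117 and 139 for the interactions, and 267 and 69 shared with TGFβ and in the interaction.

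Log2 odds of event types moved as follows. With a mean PSI between 0.05 and 0.95 (200 calls in SCR), skipped exons among calls were −0.22, 0.72 and 0.68 in SCR, sh1 and sh2 untreated and first exons 0.56, −0.39 and −0.30. Read in every library, skipped exons were 0.19 (turned), 0.34 and 0.40, and first exons 0.43 and 0.44 in sh1 and sh2 (both turned). Higher against lower, these gave −1.36 (skipped) and 1.05 (introns) in SCR, 0.62 (first exons) in sh1, and −0.32 and 0.57 (skipped, first exons) in sh2. With 1 event per gene and type skipped exons were 0.47 (turned), 0.95 and 0.91, and 0.0078 higher against lower in sh2 (turned), where taking the smallest p favours types with many events per gene.

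Read in every library, 30 list tests passed against 18. In SCR these gave 7 splicing regulators (adjusted p = 0.11), 8 actin (0.00636), 4 matrix (0.0461) and 6 vesicle genes (0.0461). In sh1 these gave 12 vesicle genes (0.00757), and in sh2 14 splicing regulators (0.177), 12 actin (0.114) and 11 vesicle genes (0.0848). Without matching on events per gene, 4 actin (0.0407) and 4 vesicle genes (0.0293) passed in SCR, 6 adhesion (0.0148) and 7 vesicle genes (0.0104) in sh1, and 8 adhesion genes (0.00582) in sh2. Same-numbered libraries correlated between −0.0186 and 0.0348, 0 of 45 pairs over 0.1 (median 0.00568, against −0.00371 for different numbers). Of 18 libraries, 12 correlated best with their own number, although only 45 pairs shared a number and 90 did not. Some pairing by number may thus be present, which the main model leaves out. The replicate block gave 220, 340 and 285 calls for TGFβ in SCR, sh1 and sh2, with 4 EMT genes in SCR (0.0693), 7 vesicle genes in sh1 (0.0429) and 9 adhesion genes in sh2 (0.024).

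With 1 library left out, counts were 253 to 340, 419 to 495 and 336 to 379 for TGFβ in SCR, sh1 and sh2, 597 to 693 and 1020 to 1142 for sh1 and sh2 untreated, 491 to 622 and 696 to 811 with TGFβ, and 288 to 364 and 295 to 377 for the interactions. Log2 odds among calls were, for skipped exons, −0.88 to −0.15, −0.12 to 0.16 and 0.064 to 0.20 in SCR, sh1 and sh2, and for first exons 0.23 to 0.60, −0.15 to 0.17 and −0.061 to 0.11. Higher against lower, they were −1.90 to −0.22, −1.05 to −0.34 and −0.24 to 0.23, and −0.25 to 1.51, −0.38 to 0.67 and −0.062 to 0.52. List counts were 4 to 6 EMT genes in SCR and 7 to 10 splicing regulators and 5 to 7 vesicle genes in sh1. In sh2 they were 9 to 12 actin, 7 to 10 adhesion, 4 to 8 matrix and 8 to 12 vesicle genes, and 9 to 21 tests passed. Of uncalled events with TGFβ in SCR, FGFR2 gave 0 without SCR TGFβ replicate 3 (up to 0.5), which is no turn. PLEKHA1 turned (−0.00914 without SCR untreated replicate 1, up to 0.0326), as did SLK in untreated cells. The SLK exon gave −0.00749 without SCR untreated replicate 3 and −0.0155 without sh1 untreated replicate 3 in sh1 (up to 0.0402), and −0.0186 without sh2 untreated replicate 1 in sh2 (up to 0.116).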

Other observations

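The fits on events read in every library, which chose the genes of this part, were chosen after the result was seen. Retained introns of several genes outside the lists moved with TGFβ in SCR cells. An intron of PSMC3IP, a recombination factor, fell by 0.550 (adjusted p = 0.00727), from 0.829 to 0.279, and an intron of GLIPR1 by 0.382 (adjusted p = 0.00438). Introns of NFE2L1, a transcription factor that drives proteasome genes, and of the uroplakin gene UPK3B rose, by 0.362 (adjusted p = 0.0353) and 0.329 (adjusted p = 0.013). An intron of PODXL, the sialomucin podocalyxin (chromosome 7, 131193787 to 131194124), fell by 0.348 with TGFβ in SCR (adjusted p = 0.00139), by 0.373 in untreated sh1 cells (adjusted p = 0.000527) and by 0.651 in untreated sh2 cells (adjusted p = 2.58e-06). For UPK3B the intron also rose with TGFβ in the knockdown lines, by 0.550 in sh1 (adjusted p = 6.71e-05) and 0.342 in sh2 (adjusted p = 0.00785).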
